A study of Mus musculus with 2 samples.

How the data were processed

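H3K9me3 ChIP-seq was measured in 2 libraries from embryonic mouse heart at day 14.5, which the labels give as biological replicates of 1 group with 3 and 2 technical replicates and a size range of 300 to 500 bp. The authors deposited 4 peak lists in narrowPeak format on mm10, 1 for each replicate, 1 for the whole series and 1 of replicated peaks. Per the file headers, each replicate's list was made from its own alignment and further files, of which 1 served both replicates, so the lists of the replicates are not fully separate. Per the file headers, the replicated list was derived from the whole-series list and the lists of both replicates. The deposited signal value is a score of the peak's enrichment, whose scale is not stated. The deposited significance columns are −log10 p and −log10 q of each peak. The smallest −log10 p in any list was 2.03, so each list holds peaks above a minimum only. The aligner, peak caller, thresholds and the rule for replicated peaks are not given in the sources used here. The lists hold no read counts, so depth is unknown and no interval for a signal value could be given.

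Genes and exons came from GENCODE vM21 for the mouse genome build of the peaks, and sequence, soft-masked repeats and GC content from the matching reference genome, whose masking program is not given in the sources used here. Comparisons used the 19 autosomes, X and Y, and the protein-coding genes numbered 21911. Overlaps were computed with bedtools 2.31.1, and other steps with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and numba 0.67.0. Figures were drawn with matplotlib 3.10.9. Lists were overlapped by at least 1 bp. Expected overlaps and feature shares came from 100 circular shifts along each chromosome. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Spearman's rho used the strongest overlapping signal value in each replicate, and its spread came from 100 resamples of chromosomes.

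The groups, comparisons, 13 gene lists and main alternatives were chosen before the data were examined. The list test compared the share of genes with at least 1 bp of a replicated peak in the gene body with 10000 random lists of the same size, matched on length in 20 bins. It gave a two-sided permutation p, of which 0.0002 is the smallest possible, with Benjamini-Hochberg adjustment over the 13 lists. Clustered Zfp genes had at least 2 other Zfp starts within 500 kb. The H3K9 machinery list named 24 genes and matched 23, since 2 of its names are names of 1 gene, given as Fam208a in the annotation. The other lists written out by name matched all of their 44 imprinted, 37 germline, 37 cardiomyocyte, 32 other heart, 32 other lineage and 28 housekeeping genes. First and last exons were compared with a two-sided exact binomial test on genes with a peak on 1 of them alone. Domains joined peaks across gaps of up to 5 kb.

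Named genes followed a rule. Among protein-coding genes of at least 1 kb covered in both replicates, it took the 10 with the largest covered percent and up to 3 per list. It added the genes at the 5 peaks with the highest signal value and at the 5 longest domains, and it allowed any member of the imprinted, cardiomyocyte, housekeeping and machinery lists. Genes named outside it are said to be so. Values per gene are the covered percent in each replicate, as mean and SD.

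Alternatives were whole-series peaks, a −log10 p of at least 5, leaving out each replicate, a window of 1 kb on each side of transcription starts, rotations of a list along the gene order (21910 of them), random lists not matched on length, other overlap rules and equal numbers of peaks. Peaks found in both replicates, first exons alone and gaps of 2 and 10 kb were added after the data were seen. Uniqueness was the share of 50-base windows, taken each 10 bases, that occur once in the reference. The list test was tested on simulated data with 100 planted genes, where 125 list genes with a peak were expected and 125 were found. With 100 null lists, 4 of random genes and 6 of long genes fell below 0.05, and 100 of the long lists did so without length matching. The simulated peaks were placed at random, and the null lists held scattered genes. How the list test behaves for neighbouring genes under clustered peaks was thus not checked. Peaks on 19 scaffolds outside the chromosomes entered the overlaps between lists and were left out of comparisons by gene, feature and chromosome, since they are part of no chromosome. No region was removed for high background, since no such list was at hand.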

Results

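Trimethylation of lysine 9 on histone H3 (H3K9me3), a mark of heterochromatin and of silenced genes, was mapped by ChIP-seq in the heart of mouse embryos at day 14.5. The 2 libraries were biological replicates of 1 group, each made from heart tissue pooled from embryos of both sexes. Replicate 1 combined 3 technical replicates and replicate 2 combined 2. Replicate 1 had 62374 peaks covering 21.3 Mb, and replicate 2 had 32630 peaks covering 10.1 Mb of the mm10 genome. The authors' list of replicated peaks held 24514 peaks covering 10.8 Mb, or 0.402% of the genome, with a median width of 359 bp. The peak lists carry no read counts, so the depth of either library is unknown, and the intervals given below cover counting error only. With 1 group and no other group to compare it with, the design asks where the mark lay and how far the replicates shared it.

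Peaks of H3K9me3 lay on zinc finger, protocadherin, vomeronasal receptor and imprinted genes more often than on other genes of the same length. Of 235 Zfp genes that sit in clusters, 108 (46.0%) held a replicated peak in the gene body, against a mean of 10.5% in random lists matched on length, a 4.36-fold excess. Among 156 Zfp genes outside such clusters, 53 (34.0%) held one, a 1.82-fold excess. Vomeronasal receptor genes held one in 72 of 326 cases (22.1%), 2.56-fold above random lists, and in the peaks of replicate 1 alone 34.7% did. Clustered protocadherin genes held one in 48 of 56 cases (85.7%), 2.72-fold above random lists, and imprinted genes in 33 of 44 cases (75.0%), 3.36-fold above them. For these 5 lists the two-sided permutation p, adjusted over the 13 lists tested, was 0.00052, from an unadjusted p of 0.0002, the smallest that 10000 random lists allowed. The same 5 lists were high in each replicate's own peaks, with 58.3% and 45.5% of clustered Zfp genes and 92.9% and 87.5% of protocadherin genes in replicates 1 and 2. Across all 21911 protein-coding genes, 3693 (16.9%) held a replicated peak, and 28.0% and 19.07% held a peak of replicates 1 and 2. With replicate 2 left out the excess of clustered Zfp genes was 2.88-fold. Against lists not matched on length and against rotations along the gene order it was 2.73-fold in each case. The protocadherin excess was 5.08-fold and 5.09-fold in these 2 settings. The vomeronasal excess was 1.31-fold against random lists not matched on length (adjusted permutation p 0.0319). It was also 1.31-fold against rotations along the gene order, which keep the clustering and do not match length, with an adjusted p of 0.297 (range over 9 alternatives 0.000433 to 0.297).

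**Figure D1:**
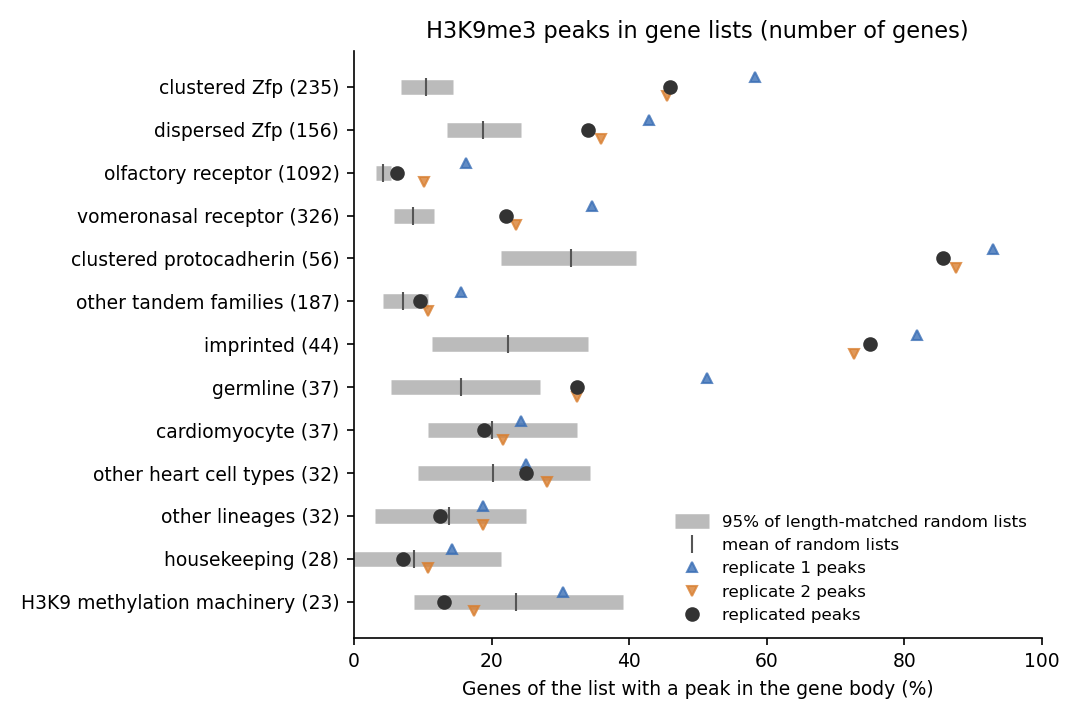
Percent of the genes of each list with a peak in the gene body, for the replicated peaks (black) and each replicate's own peaks (triangles), against 95% of random lists matched on gene length (grey bars) and their mean (vertical lines). Replicated peaks lay on 85.7% of clustered protocadherin, 75.0% of imprinted and 46.0% of clustered Zfp genes, and on 18.9% of cardiomyocyte genes.

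The 3 clustered Zfp genes with the largest covered percent held replicated peaks over most of their length. Zfp110 (chromosome 7, 12834761 to 12850577) was covered over 80.3% of its gene body by replicated peaks, and the replicates' own peaks covered 71.8% ± 12.4 (SD, n = 2). Zfp873 (chromosome 10, 82048123 to 82064745) was covered over 79.99% (replicates 72.8% ± 12.4, SD, n = 2) and Zfp68 on chromosome 5 over 67.1% (57.2% ± 10.5, SD, n = 2). Outside the clusters, coverage was highest at Zfp90 with 44.5%, Zfp369 with 33.9% and Zfp386 with 32.8% (replicates 40.5% ± 8.04, 29.9% ± 14.3 and 29.4% ± 4.49, SD, n = 2). With replicate 1 left out Zfp369 was covered over 19.8%, less than Zfp386 with 26.3%. Vmn1r65, Vmn1r70 and Vmn1r82 on chromosome 7 were covered over 43.5%, 26.3% and 21.3%. Vmn1r70 was covered over 16.3% with replicate 1 and over 44.1% with replicate 2 left out, which changed its place among them. Of 1092 olfactory receptor genes, 68 (6.23%) held a replicated peak, led by Olfr399, Olfr398 and Olfr139 on chromosome 11 with 37.5%, 29.8% and 22.7% covered. This share was 1.46-fold the mean of length-matched lists (4.25%, adjusted permutation p 0.00303), and the direction turned to 0.369-fold against lists not matched on length and against rotations along the gene order. Both shortfalls passed the threshold (adjusted permutation p 0.00052 and 0.000297). The observed share was 6.23% in each setting, and only the random mean changed, from 4.25% to 16.9%. Neither of these 2 settings matches length, and the median length of the olfactory receptor genes was 5988 bp. The turn of direction thus follows from length matching, and no lack of the mark for genes of this length is concluded. With peaks found in both replicates the olfactory excess was 1.24-fold and did not pass the threshold (adjusted permutation p 0.245). Over 9 alternatives the adjusted p ranged from 0.000297, which belongs to a shortfall, to 0.825. Olfactory receptor genes with a peak of the replicate's own numbered 178 (16.3%) in replicate 1 and 111 (10.2%) in replicate 2. In the other tandem families 18 of 187 genes (9.63%) held one, 1.35-fold the random mean with an adjusted permutation p of 0.331 that ranged from 0.0152 to 1 over 9 alternatives, with folds from 0.570 to 2.75. In the peaks of replicate 1 alone 29 of these genes (15.5%) held one. Of these genes Psg29, Obox8 and Rhox13 were covered most, over 37.9%, 17.2% and 10.4%. Psg29 was covered over 20.7% with replicate 1 left out, and Obox8 over 49.6% with replicate 2 left out, above Psg29 with 44.5%.

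On clustered Zfp genes the peaks lay far more often on the last exon, which holds the zinc finger array of these genes, than on the first. Of 234 clustered Zfp genes with several exons, 85 (36.3%, exact 95% interval 30.2 to 42.8) held a replicated peak on the last exon and 2 (0.855%, 0.104 to 3.05) on the first exon, a 42.5-fold difference. The peak was on the last exon alone in 84 genes and on the first exon alone in 1 gene (two-sided exact binomial test, p = 4.45e-24). Last exons of these genes had a median length of 2604.5 bp and held 195 peak bases per kb, and first exons had a median length of 142.5 bp and held 2.65. In 1 kb windows centred on the transcript's end and start, 48 clustered Zfp genes held a peak around the end and 3 around the start. This was a 16-fold difference (exact binomial p = 4.36e-12). These windows reach outside the gene and are not counts of peaks on the exons alone. With replicate 2 left out, the difference between the exons of clustered Zfp genes was 27-fold. Dispersed Zfp genes held a peak on the last exon in 28 of 153 cases and on the first exon in 1 case (exact binomial p = 1.12e-07). Among 19895 other protein-coding genes the last exon held one in 1.47% and the first exon in 0.669%, a 2.195-fold difference. Their last exons were longer, with a median of 1106 bp against 204 bp. Per kb the direction was the opposite, with 5.2 peak bases on last exons and 10.1 on first exons. Within 1 kb of the transcription start, the excess of clustered Zfp genes over random lists was 1.01-fold (adjusted permutation p 1, range over 9 alternatives 0.000297 to 1), and that of dispersed Zfp genes was 2.497-fold (0.183, same range). Genes of a cluster are not independent, so these p-values describe the 2 libraries and not a population of genes.

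**Figure D2:**
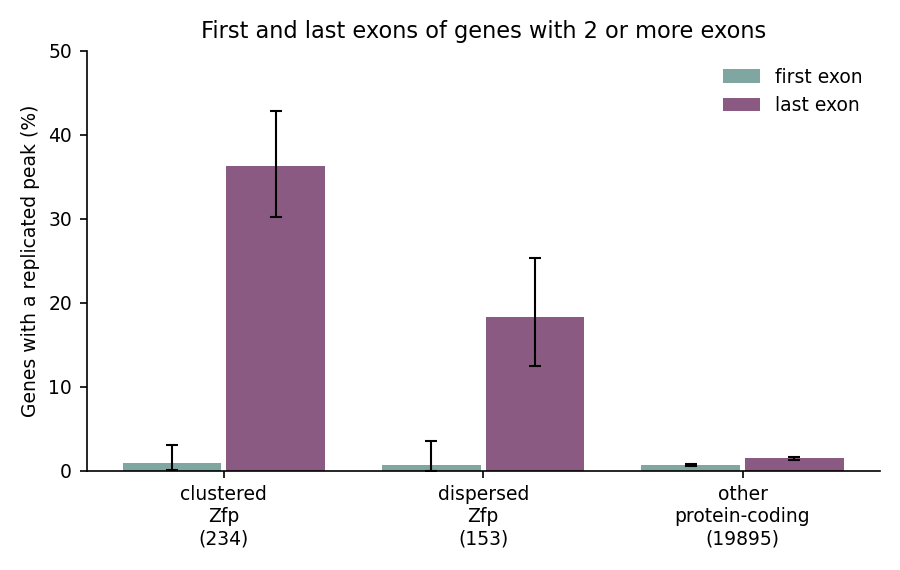
Percent of genes with a replicated peak on the first exon (green) and on the last exon (purple), for clustered Zfp, dispersed Zfp and all other protein-coding genes with 2 or more exons, with the number of genes in brackets. Error bars are exact 95% intervals for counting error, and last exons of clustered Zfp genes held a peak in 36.3% of genes.

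In the protocadherin cluster, H3K9me3 lay on the first exon of most Pcdha, Pcdhb, Pcdhga and Pcdhgb genes and of no Pcdhac or Pcdhgc gene. The cluster spans 911.7 kb of chromosome 18 (36930184 to 37841873) and held 211 replicated peaks. A peak lay on the first exon of 11 of 11 Pcdha, 18 of 22 Pcdhb, 12 of 12 Pcdhga and 6 of 6 Pcdhgb genes, and of 0 of 2 Pcdhac and 0 of 3 Pcdhgc genes. Each Pcdhb gene had a single exon in the transcript used, so its first exon is also its last. Pcdhb9, Pcdhb11, Pcdhb15 and Pcdhb16 were the Pcdhb genes without one, and these were named after their values were seen. Each of them held a whole-series peak on that exon, so it lacked a replicated peak only. No Pcdhac or Pcdhgc first exon held a whole-series peak. Pcdhb21 was covered over 66.7% of its gene body (replicates 56.4% ± 7.17, SD, n = 2), Pcdhb22 over 34.5% (30.2% ± 22.8, SD, n = 2, and 14.1% with replicate 1 left out) and Pcdhb19 over 32.3% (27.7% ± 5.14, SD, n = 2). The median first exon in the cluster was 2612 bp long and 28.8% covered. Peaks lay on 47 of 56 first exons (83.9%), against 7.24% in random lists matched on first exon length, an 11.6-fold excess (adjusted permutation p 0.00087). Of the 34 genes with several exons, 29 held a peak on the first exon and none on the last exon, which the genes of a group share. These genes overlap, share exons and lie in 1 locus, and the first exon test was chosen after the gene body results were seen.

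**Figure D3:**
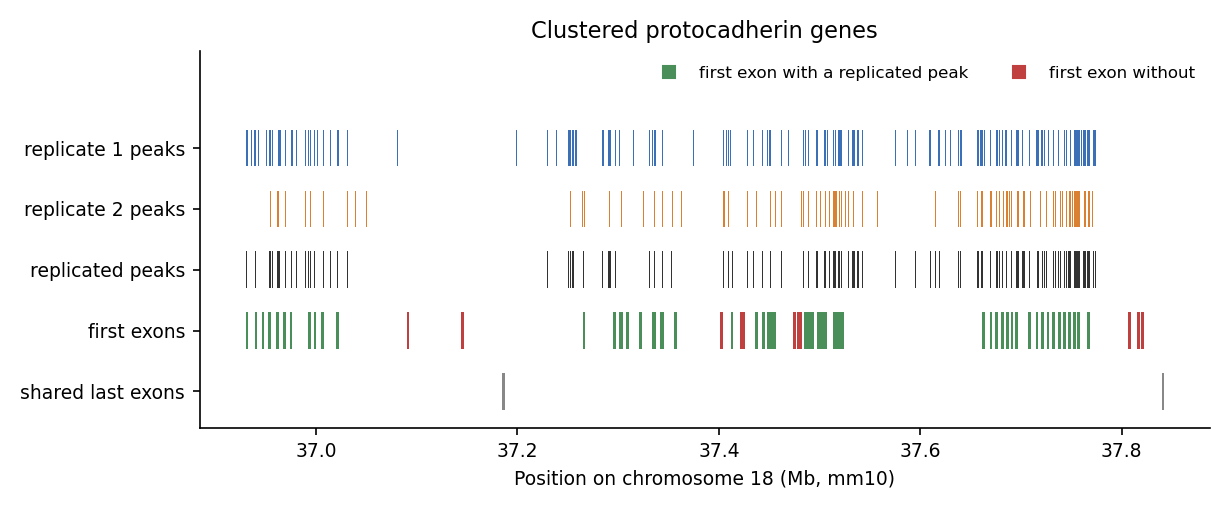
Map of the protocadherin cluster on chromosome 18 (mm10) with the replicated peaks, the peaks of each replicate and the first exons of the 56 genes. Replicated peaks lay on 47 of the 56 first exons, and on none of those of the Pcdhac and Pcdhgc genes.

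Many imprinted genes carried the mark on the first exon. Nnat (chromosome 2, 157560078 to 157562522) was covered over 63.7% of its gene body (replicates 65.6% ± 7.4, SD, n = 2), Peg13 on chromosome 15 over 48.1% (42.6% ± 8.14, SD, n = 2) and Nap1l5 on chromosome 6 over 38.8% (31.4% ± 7.78, SD, n = 2). A replicated peak lay on the first exon of Cdkn1c, Gnas, Magel2, Mcts2, Mest, Mkrn3, Nap1l5, Nnat, Peg10, Peg3, Plagl1, Sgce, Snurf, Usp29 and Zrsr1. The overlap with the first exon was 14 bases at Snurf, 17 at Sgce and 21 at Cdkn1c, and at least 131 bases at the other genes. At Magel2, Mcts2, Mkrn3, Nap1l5 and Zrsr1 it took in all peak bases of the gene body, so the first exon adds no information there. No replicated peak lay in the gene body of Dlk1, H19, Igf2, Mirg, Ndn, Peg12, Phlda2, Rasgrf1, Rtl1, Ube3a or Zim1. The first exons with a peak were 15 of 36 in protein-coding members (41.7%), against 1.86% in random lists, a 22.4-fold excess (adjusted permutation p 0.00087). Several imprinted genes overlap and share peaks, as Nnat does with Blcap, and after merging overlapping genes 24 of 35 loci (68.6%) held a replicated peak.

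Of 37 germline genes, 12 (32.4%) held a replicated peak, 2.09-fold above random lists (15.5%, adjusted permutation p 0.0193), and 19 (51.4%) held a peak of replicate 1. Taf7l on the X chromosome was covered over 7.23% (replicates 6.42% ± 0.622, SD, n = 2), Zfp42 on chromosome 8 over 5.35% (4.50% ± 1.01, SD, n = 2) and Dazl on chromosome 17 over 3.94% (4.61% ± 0.655, SD, n = 2). The peak lay on the first exon in 5 genes (13.5%, against 0.511% in random lists, a 26.5-fold excess with an adjusted permutation p of 0.00087). These were Dazl, Ddx4, Mael, Sycp2 and Taf7l, of which Ddx4, Mael and Sycp2 were named after their values were seen. The gene body excess did not pass the threshold with peaks found in both replicates (2.05-fold, adjusted permutation p 0.0745) or with rotations along the gene order (1.92-fold, 0.0714), and over 9 alternatives the adjusted p ranged from 0.00087 to 0.0745.

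Genes of the heart held replicated peaks within the range of random lists. None held one on the first exon, where the mean of random lists was 0.826% for cardiomyocyte and 0.477% for other heart genes. At such low shares an absence was likely in lists of this size. The other lineage, housekeeping and machinery lists had no peak on a first exon either. Of 37 cardiomyocyte genes, Cacna1c, Gja5, Ldb3, Myl4, Scn5a, Tpm1 and Ttn held a replicated peak (18.9% against 20.1%, 0.942-fold, adjusted permutation p 1), while Myh6, Myh7, Tnnt2, Actc1, Nkx2-5, Gata4, Tbx5 and Nppa held none. Coverage of the cardiomyocyte genes was highest at Tpm1 with 2.02% (replicates 1.90% ± 0.116, SD, n = 2), followed by Scn5a with 1.40% (1.32% ± 0.377, SD, n = 2) and Myl4 with 1.13%, or 0.679% with replicate 1 left out. Among 32 genes of other heart cell types, 8 (25%) held one, 1.24-fold the random mean (adjusted permutation p 0.793), with Pdgfrb covered over 3.04%, Flt1 over 1.28% and Wt1 over 1.16%. With replicate 1 left out Pdgfrb was covered over 0.852%, Flt1 over 1.24% and Wt1 over 0.669%, so the order of these genes rests on replicate 1. Of 32 genes of other lineages 4 held one (12.5%, 0.904-fold, adjusted permutation p 1). These were Snap25, Syt1, Pax7 and Hnf4a, the last named after its value was seen. Among 28 housekeeping genes Tbp and Gpi1 held one (7.14%, 0.818-fold, adjusted permutation p 1), and 14.3% held a peak of replicate 1. Of 23 genes of the H3K9 methylation machinery, Atf7ip, Smchd1 and Fam208a held one (13.04%, 0.554-fold, adjusted permutation p 0.456), and 30.4% held a peak of replicate 1. The direction of each of these 5 lists changed with at least 1 other setting, so no excess or shortfall was detectable for them.

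The 10 genes of at least 1 kb with the largest covered percent included Ugt1a1, Il3ra, Klf14, Mroh2a and Asmt. Replicated peaks covered 92.8% of Ugt1a1 (chromosome 1, 88211959 to 88218997; replicates 90.7% ± 4.81, SD, n = 2) and 84.2% of Mroh2a, its neighbour (81.2% ± 4.62, SD, n = 2). Il3ra on chromosome 14 was covered over 90.05% (80.9% ± 17.6, SD, n = 2), Klf14 on chromosome 6 over 86.8% (81.6% ± 8.95, SD, n = 2) and Asmt on the X chromosome over 82.5% (79.7% ± 1.72, SD, n = 2). Gm21738, Scgb1b24 and Scgb2b24 were covered over 81.7%, 81.3% and 81.1%, and Zfp110 and Zfp873 were the other two. Scgb2b24 differed most between replicates, with 82.1% covered in replicate 1 and 31.9% in replicate 2.

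The highest signal value of a replicated peak was 11.95, within 1 kb of the start of Klf14 (chromosome 6, 30956225 to 30958786), with 9.90 and 12.3 in replicates 1 and 2. Peaks at the start of Tcfl5 (chromosome 2, 180642564 to 180644143) and in an exon of Zfp810 (chromosome 9, 22278047 to 22281106) followed, both with 11.3. A peak on chromosome 12 (20229934 to 20234500) had 10.98 and lay 275093 bp from the nearest protein-coding gene, Gm21863. A peak that overlapped Slc17a7 (chromosome 7, 45168618 to 45171950), with its summit in an intron or other part of a gene body, had 10.3.

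Most domains were single peaks, some peaks gathered in larger domains, and the longest lay in the protocadherin cluster. With gaps of up to 5 kb joined, 59 peaks over the Pcdhga genes formed a domain of 108.4 kb (chromosome 18, 37669379 to 37777788), and 38 peaks from Pcdhb17 to Pcdhb22 formed the next, of 59.1 kb. A domain of 54.3 kb on chromosome 4 (121997676 to 122051937) lay 375572 bp from the nearest protein-coding gene, Gm12887, a domain of 52.7 kb on chromosome 10 overlapped AU041133, and a domain of 50.8 kb on chromosome 16 lay 308644 bp from Olfr161. There were 17261 domains on the chromosomes, of which 13712 were single peaks and 405 held at least 5 peaks. Those 405 domains held 3276 peaks, 13.5% of the replicated peaks on chromosomes. Placing the peaks at random 20 times gave a mean of 0.4 and at most 2 such domains. Some neighbouring peaks nearly touched, as those at 37254061 to 37255615 and 37255658 to 37256254 on chromosome 18. Random placement treats each peak as separate, and the lists cannot tell separate peaks from parts of a single marked stretch. The contrast thus does not show that separate peaks gather. The count of 405 moved between 192 and 1256 with the peak list, threshold and gap, and it was 524 with replicate 1 and 1256 with replicate 2 left out.

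Chromosomes 7 and 17, which carry 79 and 39 of the clustered Zfp genes, had 2.04 and 1.64 times the replicated peak bases per Mb of the autosomes together. Density did not follow the number of these genes throughout, as chromosome 13 with 26 was at 1.03 times and chromosome 5 with 6 at 1.34 times. Without peaks within 500 kb of a clustered Zfp gene the highest autosome was still at 1.82 times. Chromosome 14 was the lowest autosome, at 0.588 times. The X chromosome had 812 replicated peak bases per Mb, against 4382 on the autosomes, a ratio of 0.185 that lay below each autosome. In the replicates' own peaks the ratio of the X chromosome was 0.382 and 0.268. The Y chromosome held 5 replicated peaks, and 6.19% of its 50-base windows occurred once in the reference, against 83.98% to 93.2% on the autosomes.

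**Figure D4:**
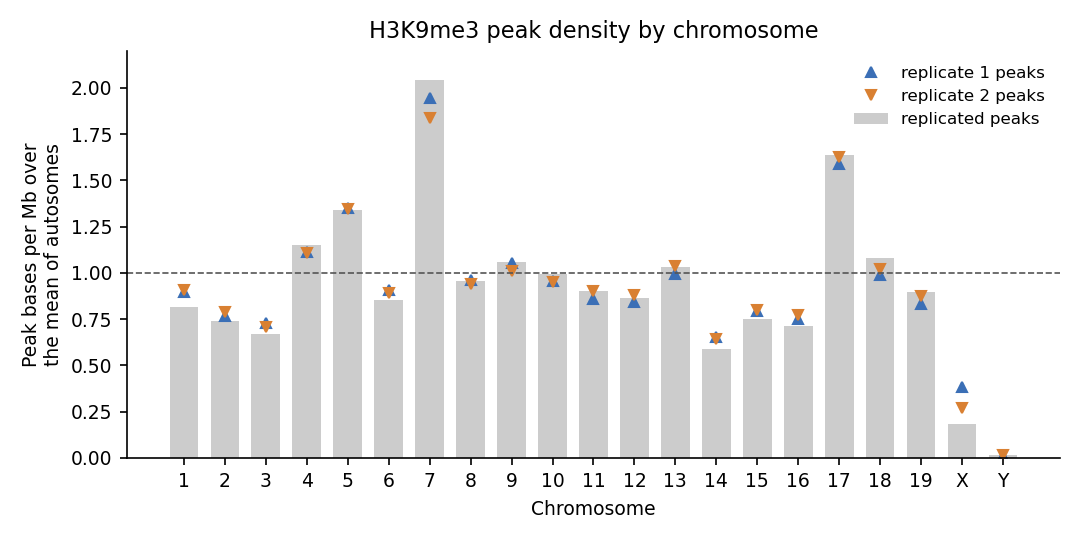
Peak bases per Mb of each chromosome divided by the value for all autosomes, for the replicated peaks and for the peaks of each replicate. Chromosomes 7 and 17 were highest, at 2.04 and 1.64 in the replicated peaks, and the X chromosome was at 0.185.

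Between genes lay 66.0% of the 24324 replicated peak summits on chromosomes, against 58.0% (range 55.4% to 61.3%) after 100 circular shifts. Introns and other parts of gene bodies held 29.4% (shifted 37.8%), exons 3.15% (shifted 2.46%) and the 1 kb around transcription starts 1.40% (shifted 1.72%), each outside the shifted range. In the peaks of replicate 1 alone the exon share was 2.45%. Masked repeats made up 26.9% of the bases in replicated peaks and 33.8% of those in shifted peaks (SD over shifts 0.477), a difference of -6.89 percentage points. The shifted positions were not matched on uniqueness. At least 90% of windows were unique in 98.2% of replicated peaks on chromosomes. Of windows drawn at random on each autosome, 83.98% to 93.2% occurred once in the reference. The difference thus cannot tell repeats without the mark from repeats where reads have several matches. No lack of the mark in repeats is concluded from it. GC content was 45.4% in the peaks and 42.0% after shifting.

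The replicates shared peak positions far more often than shifted lists. A replicate 2 peak overlapped 17030 of 62374 replicate 1 peaks (27.3%, exact 95% interval 26.95 to 27.7), against a mean of 0.876% and at most 1.38% after shifting. A replicate 1 peak overlapped 17640 of 32630 replicate 2 peaks (54.1%, 53.5 to 54.6), against a mean of 1.68% after shifting. The bases in both lists came to 4.86 Mb, 18.3% of the bases in either. Stronger peaks were shared more often, from 14.4% in the weakest 10% of replicate 1 peaks by −log10 p to 65.4% in the strongest 10%, and from 37.1% to 86.4% in replicate 2. In replicate 1, 72.2% of peaks had a q-value of at most 0.05, and in replicate 2, 21.2% did. Across the 24514 replicated peaks, Spearman's rho between the replicates' signal values was 0.0428 (SD over 100 resamples of chromosomes 0.00584), with 0 where a replicate had no peak. That choice lowers rho by construction, since 6880 peaks had a value in replicate 1 only and 1424 in replicate 2 only. Over the 15917 replicated peaks with a peak in both replicates rho was 0.243 by signal value and 0.293 by −log10 p, and peaks are not independent replicates.

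**Figure D5:**
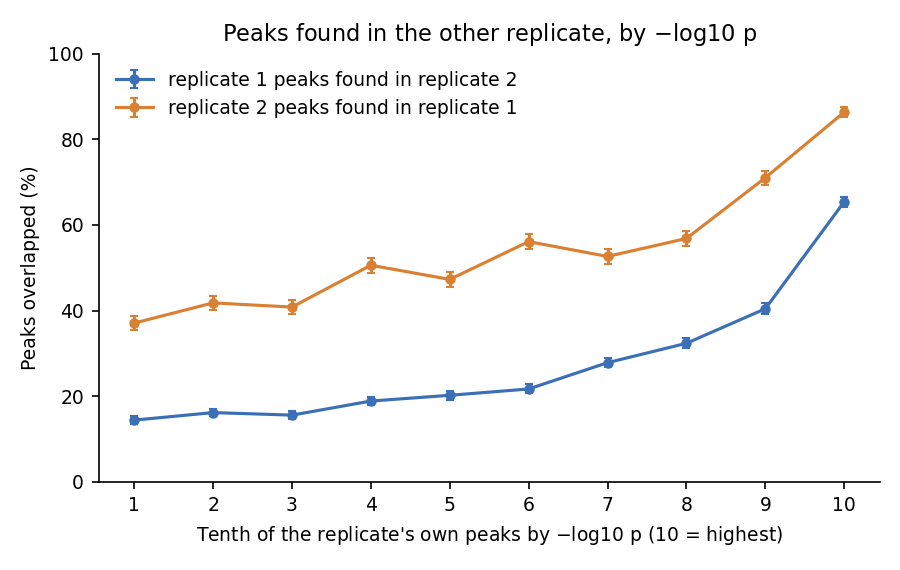
Percent of the peaks of each replicate overlapped by a peak of the other, in 10 groups of equal size by −log10 p from weakest to strongest, with exact 95% intervals. The share reached 65.4% in the strongest group of replicate 1 peaks and 86.4% in that of replicate 2.

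Each of the 24514 replicated peaks was a whole-series peak, and the replicated list held 51.5% of the 47570 whole-series peaks. Of the replicated peaks, 15917 (64.9%) overlapped a peak of both replicates, 6880 (28.1%) a peak of replicate 1 only, 1424 (5.81%) a peak of replicate 2 only and 293 (1.195%) a peak of neither. Their median −log10 p was 6.17, 5.54, 4.94 and 4.36 in that order. Of the whole-series peaks, 15650 shared at least 50% of either peak's length with a peak of each replicate, and the replicated list held each of these.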

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

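The comparison of signal values among peaks with a high −log10 p in this part was chosen after the result was seen. On unplaced or unlocalised scaffolds, which entered the overlaps between lists and no comparison by gene, feature or chromosome, there were 190 replicated peaks, and this drew attention as signal outside those comparisons. They lay on 19 scaffolds, made up 0.775% of the replicated list and numbered 51 on the scaffold with the most. Replicate 1 had 231 scaffold peaks in its own list and replicate 2 had 248. Their median −log10 p was 12.7, against 5.54 on chromosomes, while their median signal value was 3.46 against 3.35. Among peaks with a −log10 p of at least 20, the 41 scaffold peaks had a median signal value of 3.95 and the 134 chromosome peaks one of 6.64, with −log10 p not matched between them. No explanation of the scaffold peaks was tested, technical or biological.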

How the results depend on the processing

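Peaks found in both replicates, first exons and −log10 p at peaks found in both replicates were chosen after the data were seen. The folds of clustered protocadherin (2.01 to 37.7) and imprinted genes (2.31 to 24.9) kept their direction and passed the threshold under each of 9 alternatives, and the last to first exon fold of clustered Zfp genes under each of 6 (16 to 81). The lowest of these exon folds, 16, came from windows of 1 kb centred on the transcript's end and start. Among the alternative values of the comparisons planned, 102 kept their direction and call or stayed within their spread, 17 moved beyond it, 10 lost and 1 gained a call in the same direction, and 17 changed direction. Of these 17, dispersed Zfp genes on first exons also lost their call, and other tandem families without length matching gained one (adjusted p 0.0152). Except where the construction is named, the cause of the changes was not tested.

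The share of replicate 1 peaks found in replicate 2 was 17.2% with 50% overlap, 13.9% at −log10 p of at least 5, 36.9% with equal numbers of peaks and 40.6% within 1 kb, and that of replicate 2 peaks in replicate 1 was 43.7%, 64.4%, 40.1% and 68.2%. Rules that ask for more overlap lower these shares by construction. The replicated share of whole-series peaks was 80.3% at −log10 p of at least 5 and 25.5% when 50% overlap with both replicates was asked. Rho was 0.0716 by −log10 p, and over peaks found in both replicates 0.243 by signal value and 0.293 by −log10 p. Overlap and rho have no value with a replicate left out.

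Around transcription starts the fold was 1.01 for clustered Zfp, 2.497 for dispersed Zfp and 1.48 for olfactory receptor genes, no longer past the threshold (adjusted p 1, 0.183 and 0.0624), 2.75 for other tandem families, now past it (0.0291), 0 for other heart cell types and 2.97 for the H3K9 machinery. On first exons it was 1.51 for clustered Zfp, 0.857 for dispersed Zfp, 1.38 for olfactory receptor, 2.71 for vomeronasal receptor and 0 for other heart genes, and the clustered Zfp, dispersed Zfp, olfactory and vomeronasal calls were lost (adjusted p 1, 1, 0.825 and 0.0617). With peaks found in both replicates it was 1.24 for olfactory receptor and 2.05 for germline genes, whose calls were lost (0.245 and 0.0745), and 1.23 for cardiomyocyte genes.

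Under rotation along the gene order the fold was 0.369 for olfactory receptor, 1.31 for vomeronasal receptor, 0.571 for other tandem families, 1.92 for germline and 1.12 for cardiomyocyte genes, and the vomeronasal and germline calls were lost (0.297 and 0.0714). Without length matching it was 0.369 for olfactory receptor, 0.570 for other tandem families and 1.12 for cardiomyocyte genes. In both settings the genes with a peak were those of the main test. The folds changed through the random mean alone, by construction, since neither setting matches length. The cardiomyocyte fold was 1.17 at −log10 p of at least 5. With whole-series peaks the fold was 0.960 for other heart and 1.13 for other lineage genes.

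Leaving out each replicate gave 0.726 to 1.25 for other heart, 0.836 to 1.201 for other lineage and 0.837 to 1.07 for housekeeping genes, -7.02 to -5.70 points for the masked share and 0.268 to 0.382 for the X ratio. The masked difference was -7.37 with peaks found in both replicates. Of 220 alternative values for 44 named genes, 164 stayed within the spread of the replicates. Depth is unknown, so what it limits cannot be stated from these lists.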

Other observations

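The tests of first exons, of marginal peaks and of exact copies at replicate 1 peaks in this part were chosen after related results were seen, and the others before their own results were seen, on patterns noticed in the same data. The design has 1 group, so no explanation was tested by comparing groups. For the X chromosome, few Zfp clusters and fewer copies per cell, which are not technical, were examined on these lists alone.

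Replicate 1 had 62374 peaks and replicate 2 had 32630. Replicate 1 had 1.91 times as many peaks as replicate 2 in all, and 4.47 times as many (95% interval 4.35 to 4.59) at −log10 p of at least 5. The surplus was thus not confined to peaks of low −log10 p. Marginal peaks stay open as its source, since a −log10 p of 5 need not mark equal strength in libraries of unknown depth. Sequence with several exact copies in the reference was argued against, since 97.4% of the replicate 1 peaks not found in replicate 2 had at least 90% unique 50-base windows, against 97.49% of those found. That test replaced an earlier one, in which 53.8% of the unique replicate 2 peaks were found in replicate 1, and which did not bear on the surplus. Depth stays open and cannot be told apart from a difference in enrichment, since the lists hold no read counts and the test set for it decides nothing: the share found in the other replicate in the strongest 10% of peaks was 4.54 times that in the weakest 10% for replicate 1, and 2.33 times for replicate 2 too.

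Protocadherin, clustered Zfp and imprinted genes held peaks more often than genes of their length. The median share of unique 50-base windows in the peaks was 100% on protocadherin, 100% on clustered Zfp and 100% on imprinted genes. It was 100% over all replicated peaks too, so the median does not set these genes apart. At least 90% of windows were unique in 98.6% of protocadherin, 93.0% of clustered Zfp and 100% of imprinted peaks, against 98.2% of all. Reads shared between exact copies were thus argued against for most of these peaks, least so on clustered Zfp genes. How reads with several matches were treated is not known. Of the placements along the gene order, the real one included, 0.000183 gave as many protocadherin genes. For clustered Zfp or imprinted genes the share was 4.56e-05, the smallest possible. These placements keep the clustering and match neither gene length nor the overlap of gene models. For protocadherin and imprinted genes they cannot separate clustering from length or overlap. The random mean of 16.9% under rotation equals the share of all protein-coding genes with a peak by construction, so it cannot test clustering. For clustered Zfp genes the spread over rotations had its low and high ends at 10.6% and 23.8%, against 46.0% observed. Clustering alone was thus argued against for these genes. Their length would not account for this gap, as length-matched lists had a mean of 10.5%, below that under rotation. Overlapping gene models were argued against for protocadherin genes, with peaks on 83.9% of first exons. Inexact copies, the unknown read length and sequence that the reference collapses stay open, so the excess may be technical in part.

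The X chromosome had 0.185 times the replicated peak bases per Mb of the autosomes. Less unique sequence would need a far lower share of unique windows than was found, 0.838 times the autosomal median. A small number of clustered Zfp genes, of which the X chromosome has 3, was argued against as the source. The ratio was 0.19996 without peaks within 500 kb of a clustered Zfp gene, with the lowest autosome at 0.629. Fewer X copies per cell in tissue of both sexes cannot be told apart from fewer marked regions: the median signal value of X peaks with −log10 p from 5 to 8 was 1 times the autosomal one, which a control that falls with copy number would also give. That explanation may hold and stays open.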
